A study of Mus musculus with 3 samples.

How the data were processed

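Gene expression was measured on 3 single-colour microarrays of wild-type mouse bone marrow cells. All 3 arrays carry the same group label, so no comparison between genotypes or treatments was made. RNA from the sorted cells was column-purified, amplified and biotin-labelled, per the labels' protocols. The authors summarised the arrays with RMA in Affymetrix Expression Console, per the submitters' processing notes; versions and the set of arrays normalised together are not given in the sources used here. As a method, RMA subtracts background, forces the probe values of all arrays in a run onto one distribution and summarises each probe set, so it removes most array-wide differences in brightness among arrays run together. The deposited values were read as intensities on a linear scale, since they ran from 2.82 to 18384 with none below 0, and log2 of these intensities was used throughout. The test plan, written before the data were examined, had assumed log2 values, and the transformation departs from it. Every value was positive, so no pseudocount was needed.

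The table held 35554 probe sets. Through the platform annotation, 21789 named 1 gene, 1621 named several genes and 12144 were not listed there. Only probe sets with 1 gene were used, and 21698 of them matched a mouse gene ID in a reference gene table of assembly GRCm38, with 0 symbols changed. The log2 values of probe sets of the same gene were averaged, which gave 19938 genes, of which 999 had more than 1 probe set. No coordinates are given, since the deposited table states no genome build. All 3 columns of the table belong to the 3 samples.

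Without detection calls, a background range was set from 1228 olfactory, vomeronasal and taste receptor genes, families not expected in marrow cells. A gene counted as above the background range when it exceeded the 95th percentile of these receptor genes on each of the 3 arrays. That limit describes probes that should find little target. It does not show that a gene below it is absent or that one above it is transcribed, because each probe set has its own affinity. For the same reason no single gene's level was ranked against another gene's. The tests of list levels do set probe sets of different genes side by side, and whether affinities average out over a list was not tested. Among the 999 genes with several probe sets, 278 had probe sets on both sides of the limits, and 137 of these were not above the range by their mean although a probe set was. Counting those, an alternative chosen after the data were seen, gave 7483 genes above the range.

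Before the data were examined, 32 gene lists were fixed with 496 entries, of which 444 were measured here. Symbols renamed since the annotation was made were matched through the reference table for 4 genes, and list members without a probe set of their own are not analysed here. The 28 lists with at least 5 measured genes were tested for level: the median over genes of the mean log2 value was set against 10000 random lists of as many genes (two-sided permutation test). The same lists were tested for variation: the SD over the 3 arrays of the list mean was set against 10000 random lists matched on mean level in 20 bins (one-sided permutation test). The smallest p these draws can give is 0.0002 for the first test and 0.0001 for the second. Genes within a list are not independent, so these p-values describe these 3 arrays. Single genes were tested for variation with limma 3.58.1 and statmod in R 4.3.3: the variance of each gene over the arrays, on 2 degrees of freedom, was set against the robust variance trend at its mean level (one-sided F test, 4.34 prior degrees of freedom). The p-values of these tests were adjusted by Benjamini-Hochberg with a threshold of 0.05, while those of single tests of an explanation are given unadjusted.

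The tests were run on simulated data built from the real gene means and variance trend of the 19938 genes. Genes were drawn independently, without array shifts shared by genes of a level, so the rates for real lists may differ. For the test of single genes, 21% of genes with an SD 10 times the trend and 79% of those with an SD 40 times the trend were called, beside 0.0152% of unchanged genes. Both kinds, 100 genes each, were simulated in the same run and adjusted together. Calls among the latter ease the threshold for the former, so a lone gene with an SD 10 times the trend would be called less often. For the variation of lists, 87.5% of lists moved together with an SD of 0.5 log2 reached an unadjusted p under 0.05, beside 8% of unchanged lists. For the level of lists, 77.5% of lists shifted by 1 log2 did so, beside 6% of unchanged lists.

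The genes named in the text follow a rule fixed beforehand: the first 4 measured genes of each list as written, all sort gate and sex chromosome genes, the members of a list on the rarer side of the background limit where these were 5 or fewer, and the 5 genes with the smallest variation p if none passed. Genes named outside that rule are said to be so. Alternatives were other rules for several probe sets, recentring, quantile normalisation, a 99th percentile limit, filters, other list summaries, other variance models and leaving out each array. The number of arrays limits the precision of every value, and nothing in the labels says whether the arrays came from separate animals or pools.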

Results

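Haematopoietic stem cells were profiled from bone marrow of C57Bl/6 mice aged 6 to 10 weeks. The sorted population, called KLS SLAM, was negative for mature lineage markers, CD48 and CD41 and positive for c-Kit, Sca-1 and CD150, a combination that enriches strongly for long-term repopulating stem cells. The data comprise 3 arrays of wild-type cells, called arrays 1, 2 and 3 after their replicate numbers. The series design implies a description of the expression profile of these cells and of its reproducibility, with no second group analysed here. Median intensities were 60.4, 58.0 and 56.7 on arrays 1, 2 and 3. Since the labels do not say that the arrays came from separate animals, p-values of variation between arrays concern only these samples. For lists they set the spread between arrays against that of random gene lists. Genes that are regulated together can exceed such lists, and no spread between animals enters. The p-values of list levels measure the spread between genes and hold no replicate error.

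The 3 arrays agreed closely over all genes and differed by a modest amount at each gene. Across the 19938 genes, Pearson's r was 0.940 between arrays 1 and 2, 0.951 between arrays 1 and 3 and 0.948 between arrays 2 and 3, with Spearman's rho of 0.929, 0.944 and 0.937. These correlations are across genes, which are not independent replicates. The median SD of a gene over the arrays was 0.22 log2, which corresponds to 1.17-fold. No pair of arrays was a duplicate: the median absolute difference within a pair lay between 0.248 and 0.259 log2, and between 990 and 1041 genes differed by over 1 log2. Bright genes followed a shared order of the arrays. For genes with mean levels of 9 to 10, array 1 lay a median of -0.20 log2 from the gene mean and array 3 lay 0.19 above it.

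A total of 7346 genes, 36.8% of those measured, were above the background range on all 3 arrays, beside 31 of the 1228 receptor genes that set it. With the 99th percentile of those genes as the limit the count was 3471. The limit was 6.30 log2 on array 1, 5.98 on array 2 and 5.77 on array 3, and 7838, 9802 and 11011 genes passed the limit of their own array. Without array 1 the count was 9347, so many genes missed the range on array 1 alone. A gene given below as not above the range on all arrays may be among them. Of the genes used for the sort, Kit, the stem cell factor receptor, was above it at 10.01 ± 0.23 log2 (SD, n = 3). Slamf1, which encodes CD150, was above it at 6.51 ± 0.13. Among the markers the sort excluded, Cd48 was not above it on all arrays at 5.46 ± 0.77, with values of 4.61, 5.62 and 6.14 on arrays 1, 2 and 3. Itga2b, which encodes CD41, was just above it at 6.37 ± 0.14. Ly6a, the gene of Sca-1, is not analysed here. Genes used to choose the cells check the labels and are no finding about them.

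Genes of stem cell identity stood above random gene lists. Such tests set probe sets of different affinity side by side, so a list's place among random lists describes array signal and not transcript amounts. Of 22 measured members, 19 were above the background range, and the list's median averaged 7.19 ± 0.18 log2 over the arrays (SD, n = 3). The median of its genes' means lay 1.27 log2 above that of random lists, whose central 95% ran from 5.33 to 6.60 (permutation test, adjusted p = 0.0016). Procr, the endothelial protein C receptor, was at 7.39 ± 0.38 log2. The transcriptional regulators Mecom, Hlf and Mllt3, which act in stem cell self-renewal, were at 8.09 ± 0.22, 10.49 ± 0.30 and 10.18 ± 0.41. The 3 members not above the range on every array were Hoxb5 at 6.33 ± 0.27, Nkx2-3 at 6.01 ± 0.06 and Gfi1 at 6.19 ± 0.07. Hoxb5 and Gfi1 missed it on array 1 alone. The list of progenitor markers did not differ from random lists, with 4 of 11 members above the range (permutation test, adjusted p = 0.757). Those 4 were Cd34 at 8.48 ± 0.45, the cytokine receptor gene Flt3 at 7.91 ± 0.22, Notch1 at 6.40 ± 0.18 and Cd27 at 8.76 ± 0.19. Il7r, the interleukin-7 receptor of lymphoid progenitors, was at 4.49 ± 0.15, below the limit on every array.

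Of the lists for mature blood lineages, the granulocyte list alone stood above random lists. Of its 18 members 13 were above the background range, and its median averaged 7.41 ± 0.30 log2 over the arrays (SD, n = 3). The median of its genes' means lay 1.48 log2 above that of random lists (permutation test, adjusted p = 0.0011). S100a8 and S100a9, which encode the calprotectin subunits abundant in neutrophils, were at 12.08 ± 0.31 and 12.37 ± 0.38. Mpo, the myeloperoxidase of primary granules, was at 7.90 ± 0.38. Elane at 6.18 ± 0.34, Ctsg at 6.29 ± 0.75, Mmp9 at 6.10 ± 0.43, Fcnb at 6.06 ± 0.09 and Itgam at 6.16 ± 0.52 were not above the range on all arrays. Ctsg missed it on arrays 1 and 2 and the others on array 1 alone. The cells had been sorted as lineage-negative, and the values of this list differed between arrays.

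The other mature lineages stayed within the random range. Of the erythroid list 2 of 13 members were above the background range, Slc4a1 at 6.52 ± 0.12 and the carbonic anhydrase gene Car2 at 9.79 ± 0.38, while the erythroid regulator Klf1 was at 5.15 ± 0.27, Epor at 5.90 ± 0.23 and Alas2 at 6.23 ± 0.52. Haemoglobin genes share their probe sets with one another and are not named. Of the megakaryocyte and platelet list 6 of 12 were above it, among them Pf4, platelet factor 4, at 7.23 ± 0.45 and Gp9 at 6.43 ± 0.32, with Ppbp at 6.22 ± 0.54 not above it on all arrays. The monocyte, macrophage and dendritic cell list had 4 of 16 above it, namely the lysozyme gene Lyz2 at 9.61 ± 0.61, Cd68 at 7.14 ± 0.12, Cx3cr1 at 6.58 ± 0.29 and H2-Ab1 at 6.80 ± 0.49. Its members Csf1r, Adgre1 and C1qa were at 5.38 ± 0.12, 4.86 ± 0.13 and 5.87 ± 0.21.

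Lymphoid, mast cell and stromal markers were mostly not above the background limit on all arrays. Of the B cell list 1 of 13 was above it, Cd79b at 6.56 ± 0.07, with Cd79a at 4.21 ± 0.26, Pax5 at 6.07 ± 0.16 and Ebf1 at 4.37 ± 0.32. Pax5 missed it on array 1 alone, as did Vpreb1, Vpreb3 and Igll1, named after their values were seen. Of the T and NK cell list 2 of 17 were above it, Nkg7 at 6.61 ± 0.72 and Bcl11b at 6.53 ± 0.06, with Cd3e at 6.09 ± 0.31, Cd4 at 5.65 ± 0.12, Cd8a at 5.63 ± 0.08 and Ncr1 at 3.74 ± 0.41. Of the mast cell, basophil and eosinophil list 1 of 11 was above it, Prg2 at 6.79 ± 1.14, with Cpa3 at 4.79 ± 0.28, Mcpt8 at 6.57 ± 0.70 and Ms4a2 at 4.02 ± 0.21. Mcpt8 also missed it on array 1 alone. So did Col3a1 of the stroma list and Apoa1 of other organs, both named after their values were seen. Stroma and endothelium had 4 of 13 above it, Cxcl12 at 6.37 ± 0.32, Col1a1 at 6.74 ± 0.18, Col1a2 at 6.74 ± 0.03 and Stab2 at 6.15 ± 0.14, while Lepr was below the limit on every array and Cdh5 was at 5.42 ± 0.23. Genes of other organs, which the cells should lack, still had 4 of 18 above it: Tnnt2 at 6.76 ± 0.08, Prm2 at 6.39 ± 0.13, Acta1 at 6.24 ± 0.17 and Ckm at 6.83 ± 0.21. Alb, Ins2, Myh6 and Gfap were at 4.69 ± 0.14, 5.77 ± 0.20, 5.24 ± 0.03 and 5.32 ± 0.09. Values this close to the limit were thus also given by genes of other organs. No list stood below random lists by its median. The T and NK cell list did so by its mean (permutation test, adjusted p = 0.032, and 0.032 to 0.392 over its 8 alternatives).

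**Figure D1:**
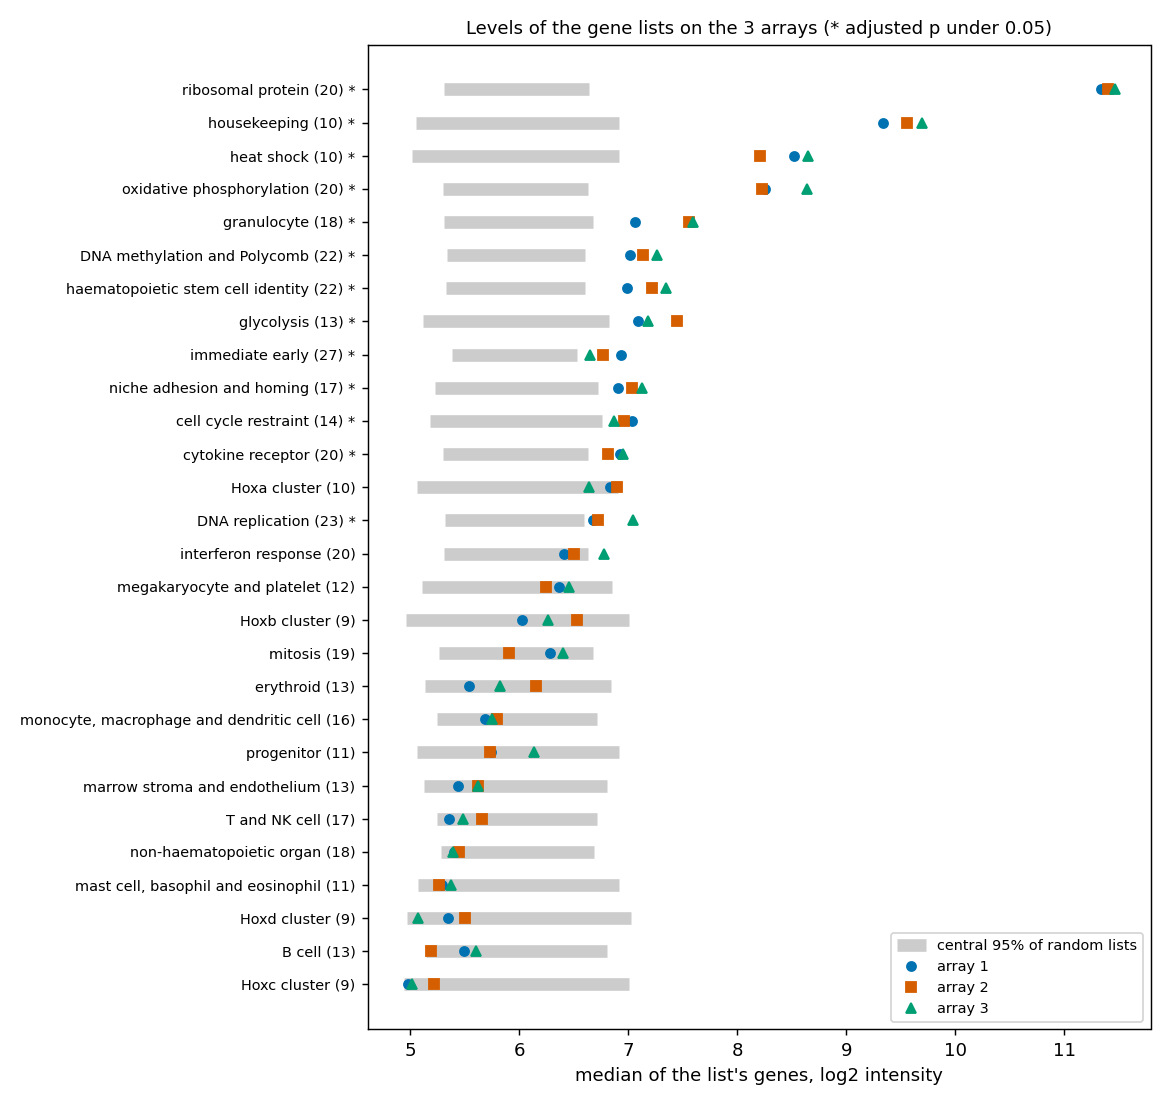
Median log2 intensity of each gene list on each array (coloured points, horizontal axis) with the central 95% of random lists of as many genes as grey bars; the number of genes is in brackets and an asterisk marks an adjusted p under 0.05. The stem cell identity list lies between 6.99 and 7.35 on the 3 arrays, and its random range ends at 6.60.

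Hox genes, which encode homeodomain transcription factors, differed by cluster in how many members were above the background range. In the Hoxa cluster 6 of 10 were above it, including Hoxa4 at 7.56 ± 0.21 and Hoxa5 at 7.98 ± 0.28, while Hoxa2, Hoxa3, Hoxa11 and Hoxa13 were not, at 5.46 ± 0.16, 6.39 ± 0.31, 5.27 ± 0.51 and 5.22 ± 0.17. In the Hoxb cluster 4 of 9 were above it, Hoxb1 at 6.62 ± 0.37, Hoxb3 at 7.06 ± 0.23, Hoxb4 at 7.68 ± 0.41 and Hoxb7 at 6.61 ± 0.14. Hoxb2, Hoxb6, Hoxb9 and Hoxb13 were below the limit on every array. In the Hoxc cluster 0 of 9 members were above it, with Hoxc4 at 5.20 ± 0.03 and Hoxc6 at 5.08 ± 0.52, and in the Hoxd cluster 1 of 9, Hoxd10 at 6.10 ± 0.28. None of the 4 cluster medians differed from random lists by the permutation test, with adjusted p of 0.143 for Hoxa, 0.532 for Hoxb, 0.154 for Hoxc and 0.231 for Hoxd. The counts of the clusters were not tested against each other.

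**Figure D2:**
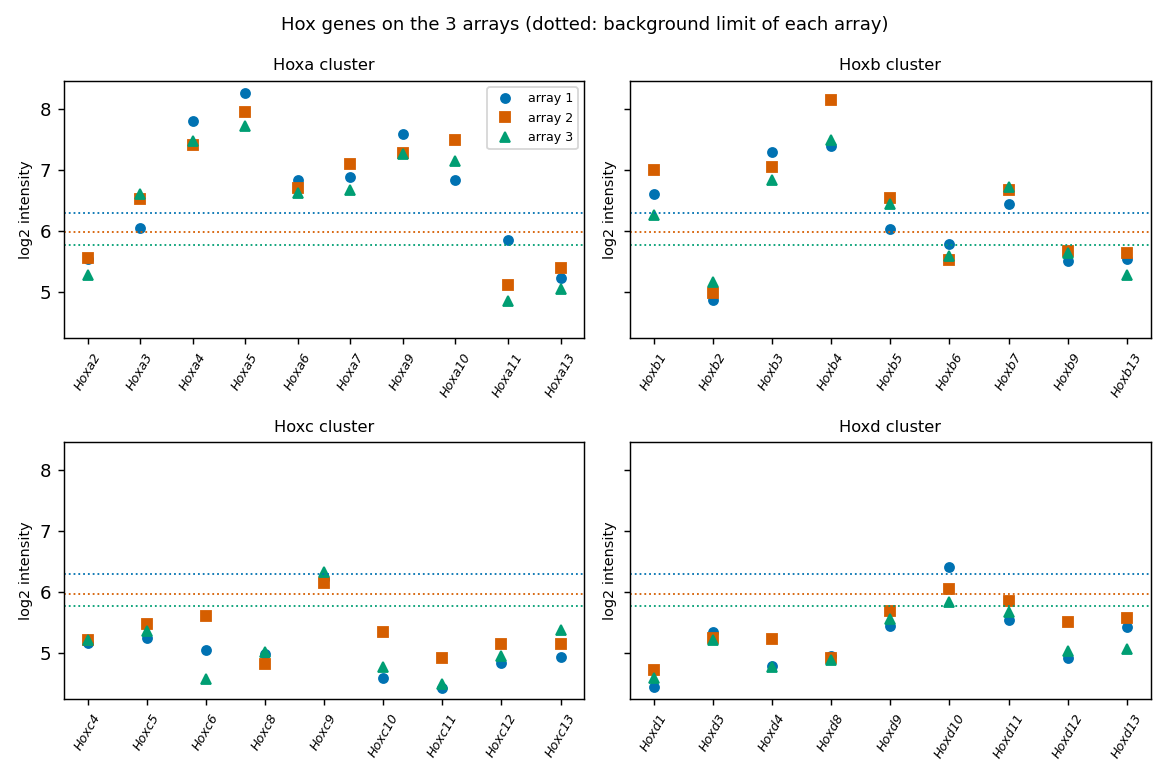
Log2 intensity (vertical axis) of each measured Hox gene (horizontal axis) on arrays 1, 2 and 3, in one panel per cluster, with each array's background limit as a dotted line. Hoxa4 and Hoxa5 lie above all 3 limits and no Hoxc gene does so on every array.

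Genes that restrain the cell cycle and genes of DNA replication stood above random lists, and the mitosis list did not. Of the mitosis list 6 of 19 members were above the background range (permutation test of its median, adjusted p = 0.617), including Mki67 at 7.05 ± 0.56, Cdk1 at 6.49 ± 0.27 and Ccnb2 at 7.21 ± 0.32. Top2a averaged 6.37 ± 0.07 over 2 probe sets that disagreed, at 7.72 ± 0.24 and 5.02 ± 0.28, and with the brighter probe set, above the range on every array, the count was 7 of 19. Of the DNA replication list 16 of 23 were above it (adjusted p = 0.0326, permutation test), including the helicase gene Mcm2 at 7.16 ± 0.02, the sliding clamp gene Pcna at 10.81 ± 0.44 and Rrm2 at 6.79 ± 0.31, with Cdc6 at 5.90 ± 0.69. Of the restraint list 10 of 14 were above it (adjusted p = 0.0349, permutation test). Among them were the cyclin-dependent kinase inhibitors Cdkn1c at 6.86 ± 0.07 and Cdkn1b at 8.55 ± 0.51 and the transcription factor Foxo3 at 7.86 ± 0.23. Cdkn2c at 5.32 ± 0.49, Rbl1 at 6.37 ± 0.76, Btg1 at 6.53 ± 0.44 and Foxo1 at 6.42 ± 0.17 were not. The restraint list lost its call without array 1 (adjusted p = 0.0849) and without array 2 (adjusted p = 0.0579), and both lists missed the threshold in permutation tests against random lists without receptor genes (adjusted p = 0.0525 for each). Over the 8 alternatives the adjusted p ran from 0.0107 to 0.0849 for restraint and from 0.0107 to 0.0525 for replication.

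Genes of protein synthesis and energy metabolism stood above random lists. All 20 measured ribosomal protein genes, all 20 oxidative phosphorylation genes and all 10 housekeeping genes were above the background range (permutation tests, adjusted p = 0.0011 for each list). Rps6, Rplp0, Rps3 and Rpl4 were at 12.74 ± 0.19, 11.30 ± 0.03, 10.99 ± 0.09 and 12.24 ± 0.31 log2, and their values are uncertain because such genes share sequence with processed pseudogenes. The respiratory chain genes Ndufs1, Sdha, Cox4i1 and Atp5b were at 7.72 ± 0.32, 9.42 ± 0.06, 9.72 ± 0.09 and 9.78 ± 0.30. The housekeeping genes Actb, Hprt, B2m and Tbp were at 12.15 ± 0.13, 8.83 ± 0.63, 12.33 ± 0.18 and 7.53 ± 0.53. Of the glycolysis list 11 of 13 were above the range (adjusted p = 0.0326, permutation test), with Hk2 at 6.30 ± 0.17, Ldha at 8.14 ± 0.27 and Pkm at 8.64 ± 0.28, while the phosphofructokinase genes Pfkp and Pfkl were at 6.15 ± 0.63 and 5.65 ± 0.26. The glycolysis call was lost without array 2 (adjusted p = 0.0663) and against random lists without receptor genes (adjusted p = 0.0521), both by permutation, with 0.0014 to 0.0663 over its 8 alternatives.

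Heat shock and immediate early genes also stood above random lists. The heat shock list had 8 of 10 members above the range (adjusted p = 0.0016, permutation test), with the chaperone genes Hsp90aa1 at 10.77 ± 0.19, Hspa8 at 11.71 ± 0.27 and Hsph1 at 7.34 ± 0.32, and the inducible Hspa1a and the small Hspb1 not above it on all arrays at 6.15 ± 0.38 and 5.42 ± 0.08. The immediate early list had 16 of 27 above it (adjusted p = 0.0021, permutation test), with Egr1 at 7.32 ± 0.66 and Junb at 6.45 ± 0.12, and with Fos at 6.08 ± 0.75 and Nr4a1 at 5.93 ± 0.22 not above it on all arrays. Its excess over random lists, 1.10 log2, was 0.73 without array 1 (adjusted p = 0.0443) and 0.73 by the list's mean (adjusted p = 0.031), with 0.0021 to 0.0443 over its 8 alternatives by permutation. The interferon response list had 10 of 20 above it and did not differ from random lists (adjusted p = 0.154, permutation test). Its members Ifit1, Irf7, Ifit3 and Ifit2 were at 6.76 ± 0.51, 5.58 ± 0.21, 6.33 ± 0.32 and 5.92 ± 0.83.

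Receptors and chromatin regulators formed the remaining lists above random. Of the niche adhesion and homing list 12 of 17 were above the range (adjusted p = 0.028, permutation test), with the chemokine receptor gene Cxcr4 at 10.27 ± 0.62, the integrin genes Itga4 and Itgb1 at 8.90 ± 0.11 and 8.84 ± 0.27, and Cd44 at 7.29 ± 0.14. Itga5, Itgal, Cdh2, Jam3 and Jam2 were not, at 5.96 ± 0.05, 5.79 ± 0.14, 5.08 ± 0.39, 6.24 ± 0.24 and 5.67 ± 0.16. Of the cytokine receptor list 14 of 20 were above it (adjusted p = 0.0345, permutation test), including Il6st at 7.82 ± 0.25, Ifnar1 at 6.77 ± 0.17 and Ifnar2 at 9.06 ± 0.06. That call was lost without array 1 (adjusted p = 0.0518) and against random lists without receptor genes (adjusted p = 0.0525), both by permutation, with 0.0224 to 0.0525 over its 8 alternatives. Of the DNA methylation and Polycomb list 19 of 22 were above it (adjusted p = 0.0011, permutation test), including Dnmt3a at 7.46 ± 0.18, Tet2 at 6.56 ± 0.30, Bmi1 at 7.56 ± 0.71 and Ezh2 at 8.51 ± 0.78. Cbx8 and Kdm6b were not above it on all arrays, at 6.03 ± 0.05 and 6.34 ± 0.29. Eed averaged 6.10 ± 0.40 over 2 probe sets that disagreed, at 7.79 ± 0.57 and 4.40 ± 0.40, and with the brighter probe set, above the range on every array, the count was 20 of 22.

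Between the 3 arrays, 1 of the 28 lists varied more than random lists of the same levels, and it was the granulocyte list. Its mean was 7.54 log2 on array 1, 8.13 on array 2 and 8.10 on array 3, an SD of 0.34 against a median of 0.12 for matched lists (one-sided permutation test, adjusted p = 0.0084). Of its 18 genes 13 were higher on both arrays 2 and 3 than on array 1, and 2 were lower on both. The neutrophil genes S100a8 and S100a9 were at 11.73 and 11.94 on array 1, at 12.31 and 12.57 on array 2 and at 12.20 and 12.61 on array 3. Ngp and Camp, of the later granules, were at 9.25 and 8.39 on array 1, 11.14 and 9.39 on array 2 and 10.40 and 9.55 on array 3, and were named after their values were seen. Mpo went the other way, at 8.29, 7.53 and 7.88. The variation rested on array 1, since without it the adjusted p was 0.905 by permutation, and it was lost when lists were summarised by their median (adjusted p = 0.814, permutation test, with 0.0028 to 0.905 over its 9 alternatives). Array 1 also stood apart in other values, with 65 receptor genes over 1 log2 above both other arrays, against 4 on array 2 and 0 on array 3, and with a background limit of 6.30 against 5.98 and 5.77. Prg2, the eosinophil major basic protein gene, at 8.08, 6.32 and 5.96, and the immediate early list, with means of 6.93, 6.64 and 6.68 (adjusted p = 0.205, permutation test, which did not pass), had their highest value on it. The mitosis list, with means of 6.33, 6.02 and 6.36, and the interferon list, with 6.53, 6.56 and 6.88, did not pass (adjusted p = 0.0952 and 0.118, permutation tests). The erythroid list did not pass either, with means of 5.86, 6.21 and 6.17 on arrays 1, 2 and 3 (adjusted p = 0.118, permutation test), and 10 of its 13 genes were higher on both arrays 2 and 3 than on array 1 and 2 lower on both. Single genes outside the granulocyte list also had their lowest value on array 1. Car1, a carbonic anhydrase gene named after its values were seen, was at 5.41, 7.10 and 7.60, Lyz2 at 9.06, 10.26 and 9.51, and Cd48, which the sort excluded, at 4.61, 5.62 and 6.14.

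**Figure D3:**
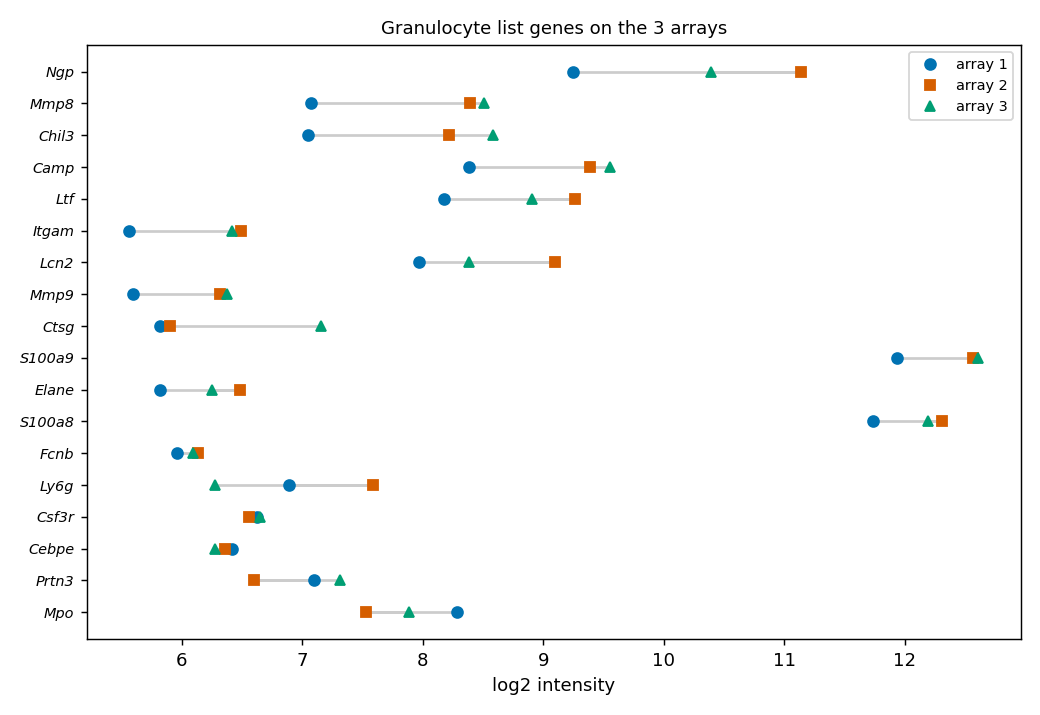
Log2 intensity (horizontal axis) of the 18 granulocyte list genes on arrays 1, 2 and 3 (coloured points), ordered by the difference between the mean of arrays 2 and 3 and array 1. Ngp is at 9.25 on array 1 and at 11.14 and 10.40 on arrays 2 and 3.

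No single gene passed the limma-based variance test over all genes, with 1017 genes, 5.10%, at an unadjusted p under 0.05 and a smallest adjusted p of 0.744. Of unchanged simulated genes 4.43% had such an unadjusted p. The test called only 21% of simulated genes with an SD 10 times the trend, in a run eased by genes at 40 times the trend. It therefore does not show that no gene varied. The 5 genes with the smallest p, none of which passed, were Xist, Olfr801, Snora20, Snord38a and Olfr578. Xist, the noncoding RNA that silences an X chromosome in female cells, was at 9.99 log2 on array 2 and at 4.64 and 4.95, below the background limit, on arrays 1 and 3. The Y-linked genes were lower on array 2: Eif2s3y was at 7.38, 5.47 and 8.65 on arrays 1, 2 and 3, Kdm5d at 7.15, 6.05 and 7.03, and Uty at 7.04, 4.99 and 6.70, with Eif2s3y and Uty below the limit on array 2. Adjusted over the list alone, Xist, in a list of 1 gene, and 2 of the 3 Y-linked genes passed (limma-based variance test, adjusted p = 0.000115 for Xist and 0.00761 for Eif2s3y and Uty), with 0 passing over all genes. Adjusted over the list alone, Cd48 also passed among the 2 sort gate negative genes (adjusted p = 0.0282, limma-based variance test) and Vpreb1 among the B cell genes (adjusted p = 0.0345), and no gene passed in any other list. Cd48 is also 1 of the 11 progenitor genes, among which it did not pass (adjusted p = 0.155, limma-based variance test). Adjustment within a list does not correct for the 32 lists, so single passes such as these can arise by chance. Vpreb1, part of the surrogate light chain of early B cells, was at 5.81, 6.38 and 9.02 on arrays 1, 2 and 3 and was named after its values were seen. Olfr801 was at 8.20 on array 1 and at 4.62 and 4.46 on the others. Snora20, a small nucleolar RNA, was at 4.40, 9.67 and 6.14.

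**Figure D4:**
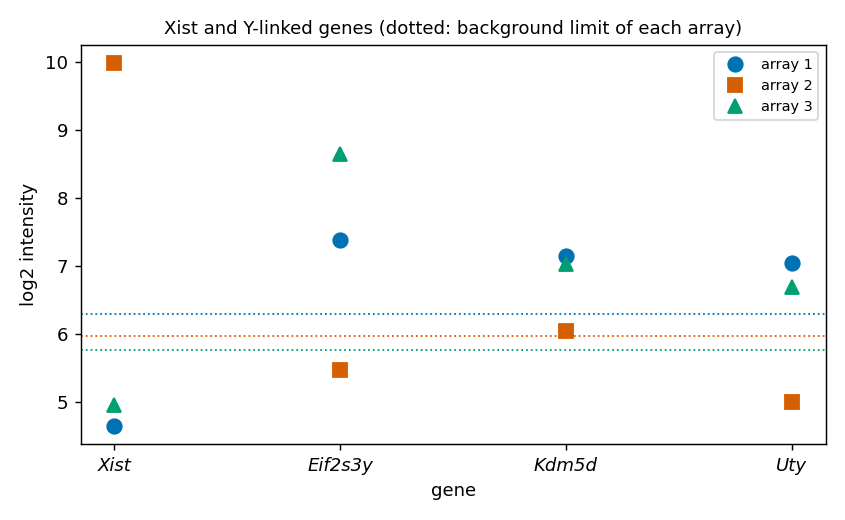
Log2 intensity (vertical axis) of Xist and 3 Y-linked genes (horizontal axis) on arrays 1, 2 and 3, with each array's background limit as a dotted line. On array 2 Xist is at 9.99 and Uty at 4.99, and on arrays 1 and 3 Xist is at 4.64 and 4.95.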

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

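The number of genes above the background range, 7346, fell to 3471 with the 99th percentile of the receptor genes, was 10260 with means over the 3 arrays set against the limit of the means, and was between 7381 and 9347 when 1 array was left out, the latter without array 1. Over genes above the background range only, the mean Pearson r of the pairs was 0.891 and the mean of the pairs' median differences 0.294 log2, against 0.946 and 0.255 over all genes. Leaving out each array leaves 1 pair, so it returned the values of the pairs, 0.940 to 0.951 for r and 0.248 to 0.259 log2 for the difference, and added no check. The number of lists above random lists, 13, was between 9 and 13 over all alternatives, and every list above them under an alternative was among the 13. The 9 came from drawing random lists without receptor genes, which raises the levels drawn. Lists below random lists numbered 0, and 1, the T and NK cell list, with the mean in place of the median. The number of lists that vary, 1, was 0 with the median as summary of a list and 0 to 1 when 1 array was left out, with 0 without array 1. The ratio of the granulocyte list's SD to that of matched lists, 2.90, was 1.49 with the median and 0.219 to 6.01 when 1 array was left out; the cause of the loss under the median was not tested. With recentring, quantile normalisation, scaling by the trend SD, another probe set rule or genes above the background range only, its adjusted p stayed between 0.0028 and 0.0459 by permutation. The count of 0 varying genes held under all 9 alternatives of the limma-based test, with 325 to 1156 genes at an unadjusted p under 0.05. That test missed most simulated genes with an SD 10 times the trend, so the count does not show that no gene varied. Mean levels of named genes moved by over 1 SD in 8 of 972 recomputations, all with the brightest probe set in place of the mean, Top2a to 7.72 and Eed to 7.79 among them. Most of the 972 could not move that far. Leaving out 1 of 3 arrays cannot shift a mean by 1 SD, and the probe set rule changes only genes with several probe sets. Of the named genes with several probe sets, only Hspa8, Pcna and Pkm did not move by that rule. No paired analysis was possible because all 3 arrays belong to 1 group.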

Other observations

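Further gene groups, chosen after the main results were seen, added to the description of the sorted cells, and the genes named from them were picked after their values were seen. All 7 genes of a transcription factor heptad of blood stem cells were above the background range, and their median stood above random lists (permutation test, adjusted p = 0.0119 over 7 added lists), though 4 of the 7 also belong to the stem cell identity list. Erg, Fli1 and Lyl1, not in any earlier list, were at 9.39 ± 0.07, 9.69 ± 0.13 and 7.37 ± 0.20 log2 (SD, n = 3). Redox defence genes had 10 of 13 above the range (adjusted p = 0.0014, permutation test), including Sod1, a superoxide dismutase gene, at 11.86 ± 0.27, Gpx1 at 10.24 ± 0.35 and Txn1 at 10.98 ± 0.57, with Nqo1 at 4.33 ± 0.25. Autophagy genes had 10 of 12 above the range and missed the threshold (adjusted p = 0.0653, permutation test). Imprinted genes (8 of 13 above the range), ABC transporters (5 of 8), p53 targets (6 of 11) and Notch and Wnt receptors or ligands (4 of 12) did not differ from random lists, with adjusted p of 0.337, 0.2, 0.342 and 0.907 by permutation. Among them Abcg2, the dye-efflux transporter of side population cells, was at 7.90 ± 0.24, Abcb1b at 6.99 ± 0.15, and the imprinted genes Meg3 and Grb10 at 7.23 ± 0.15 and 7.23 ± 0.05.

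Of the tests on 3 patterns, that of the small nucleolar RNA class itself, with and without its 2 most variable members by p, and those on quantile normalisation, on the sex of the material, on both explanations of the sex-linked genes, with values set to the limit too, and on small RNA recovery, the mean-level split of small nucleolar RNA genes, and the neutrophil tests over all measured members and by mean level, were chosen only after the result was seen.

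The granulocyte genes were lower on array 1 than on arrays 2 and 3. After quantile normalisation the adjusted p was 0.0056 by permutation and arrays 2 and 3 lay 0.536 log2 above array 1. RMA may already have matched the arrays in part, though the 5th to 95th percentiles still ran from 3.07 to 9.22 log2 on array 1 and from 2.88 to 9.44 on array 3. The mean r, 0.947 against 0.946, hardly responds to signal compression and does not show how much this step changed. A shift shared by all genes of the same level, as such compression would give, is argued against as the whole cause. Relative to lists matched on level, the list mean deviated by -0.297, 0.222 and 0.0754 log2 on arrays 1, 2 and 3. The sex of the material is argued against as the whole cause, since arrays 1 and 3, both low in Xist and above array 2 in all 3 Y-linked genes, differed by 0.566 log2 in the list mean, although Eif2s3y also differed between them, at 7.38 and 8.65. Part of that gap is shared by genes of the same level, since the deviations from matched lists were -0.297 on array 1 and 0.0754 on array 3. For mature neutrophil RNA in differing amounts, a candidate explanation, the test as planned passed: the 10 genes of a second neutrophil list above the background range on every array lay a median of 0.927 log2 higher on arrays 2 and 3 than on array 1, with 8 higher and 2 lower (one-sided permutation test, p = 0.0001, the smallest these draws can give). That choice leaves out 5 higher and 3 lower genes, whose gaps are inexact because each was within the background range on at least 1 array, and with such genes included the gap was 0.454 log2 over the 13 with a mean level above the limit (permutation test, p = 0.0046) and 0.202 over all 18 measured, with 13 higher and 5 lower (permutation test, p = 0.0586). Counts of this second list go by the mean of arrays 2 and 3, whereas those of the granulocyte list required both arrays, so they cannot be compared. Cd177 and Hp, named after their values were seen, count as higher although array 2 was below array 1. The explanation therefore stays open, and the lineage-negative gate should have removed neutrophils. S100a8 and S100a9 were higher by 0.52 and 0.65 log2. Of the second list, Retnlg and Cxcr2 were higher by 1.15 and 1.42 log2, while Lrg1 and Il1b had gaps of -1.28 and -0.60. These genes of the second list are named outside the naming rule.

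Sex-linked genes set array 2 apart from arrays 1 and 3. Noise of single probe sets is argued against, since the share of random sets of 3 genes at the same levels that lay as far below both other arrays on array 2 was 0.0002. The values are those expected if array 2 carried female material and arrays 1 and 3 male material, with Xist measured 5.04 log2 above the higher of the others and 3 of 3 Y-linked genes lower by at least 0.978 log2, though Xist on arrays 1 and 3 and Eif2s3y and Uty on array 2 were below the background limit, and with such values set to the limit the gaps were 3.70 and at least 0.72 log2. The labels used here give no sex, and of the X-linked partners, named outside the naming rule, Kdm6a and Ddx3x were 1.12 and 0.69 log2 higher on array 2 than on the mean of the others, Eif2s3x 0.16 higher and Kdm5c -0.25 from it. If the material differed in sex, the arrays would come from at least 2 animals or pools, and part of the spread between replicates could be a sex difference, which 1 array of one kind and 2 of the other cannot separate from the array itself.

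The 51 genes for small nucleolar RNAs varied more between arrays than other genes of the same level. Their median SD was 0.72 log2 against 0.22 for all genes, and the median log2 ratio of SD to trend was 1.26 against -0.14 in matched lists (one-sided permutation test, p = 0.0001, the smallest these draws can give), and 1.24 with the same p without Snora20 and Snord38a, which were among the 5 genes with the smallest variation p. A shift common to the class, as from uneven recovery of small RNA, is argued against as the whole cause, since the mean of all 51 genes had an SD of only 0.127 log2 over the arrays, against 0.116 with arrays shuffled within genes (permutation test, p = 0.432). Levels near the background range are argued against too, since the 31 such genes with a mean level above the limit had a median log2 ratio of 1.18, and the 22 above it on every array 1.08. The number of probes per probe set, not analysed here, stays open, and no biological explanation was tested. The 300 microRNA genes had a median ratio of -0.20, which was not tested. Their median level, 4.79 log2, was below the background limit of every array, against 6.41 for the small nucleolar RNA genes, so they are no like contrast.

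Some further values stood apart on a single array, without a passing test over all genes. Fos was at 6.94, 5.57 and 5.74 on arrays 1, 2 and 3 and Egr1 at 8.09, 6.96 and 6.92. Among interferon response genes, Ifit2 was at 5.28, 5.63 and 6.86.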
